A study of Mus musculus with 28 samples.

How the data were processed

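Gene expression was measured on 28 one-colour Affymetrix mouse arrays, each hybridised with biotin-labelled cRNA made from total RNA of splenic dendritic cells. The labels named C57BL/6J wild-type mice and NOX2 knockout mice, Trizol extraction and biological replicates. NOX2 is the catalytic subunit of the phagocyte NADPH oxidase and is encoded by Cybb. Each array was placed in 1 of 6 groups from its own label. Some knockout titles wrote angiotensin I where their descriptions wrote angiotensin II, which was followed. The series design stated that dendritic cells were isolated from spleen and then treated, while its title spoke of hypertension, so whether mice or isolated cells received the treatments was not settled by the sources used here. The sort or gate, the doses and the duration of treatment were not given in the sources used here.

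The deposited table held 1 log2 value per probe set and array, on the RMA scale per the submitters' processing notes, which named RMA and Partek 6.6. The RMA version, the probe annotation and the background settings were not given in the sources used here. Deposited values ran from 0.90 to 14.34 over 35556 probe sets. No further background correction, scaling or log transformation was applied for the main results, and a difference of 1 on this scale is a 2-fold difference. RMA compresses large differences and dim probe sets, so folds of dim genes may be understated. Where a called gene averaged below 5 in 1 group, a difference given as "at least" or "or lower" puts 5 in place of that mean. No detection calls or scanner intensities were used here, so signal over background was limited by a threshold on the log2 value, and the number of arrays limits the precision.

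Probe sets were named through GEO's platform annotation: 21789 carried 1 gene symbol, 1621 carried several and 12146 carried none. By Entrez identifier 21698 of the single-symbol probe sets were matched to NCBI RefSeq genes (GRCm38.p6), which changed 0 symbols. That table was used for names and gene neighbours only. Where several probe sets carried 1 gene (999 of 19938 genes), the probe set with the highest mean over all arrays was kept. Genes above 5 on at least 3 arrays were tested, which left 10452 genes. Il6 and Il23a did not reach that level, with highest values of 4.66 and 4.71 over all arrays, and were not tested.

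Differences were fitted with limma 3.58.1 in R 4.3.3, with 6 group means in 1 fit over all 28 arrays and a spread shared across groups, followed by eBayes with neither trend nor robust options. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison, and all tests were two-sided. Adjusted p values of single genes below come from limma unless another test is named. Errors after ± are SDs over the arrays of a group, and SE is limma's standard error of a difference.

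Before the data were examined, 30 gene lists were fixed, 15 of functions and 15 of cell type markers, and 28 with at least 5 tested members were analysed. They are named in the report, where cDC1 and cDC2 are conventional dendritic cells of types 1 and 2, "inflammatory" includes NF-κB genes, "immediate early" heat shock genes, "eicosanoid" aldehyde metabolism and "glycolysis" hypoxia genes. Lists for the renin-angiotensin system and for mast cells and basophils had 2 and 3 tested members and were left out. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists of a comparison. No list was called in any comparison of this fit when camera estimated the correlation from the data, and that adjusted p is given beside each list. Camera compares a list with the other tested genes, and fry tests if members move on balance 1 way. List means were tested by exact permutation of arrays, which called lists only with Hyd/HCTZ.

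The genes named were chosen by a rule fixed before the data were examined: 10 genes of the oxidase, inflammation, costimulation and oxidative stress whatever the test gave; the 8 largest rises and 8 largest falls among called genes, or the 3 smallest p values where fewer than 3 genes were called; and, for each list called by camera, up to 4 members with the smallest p and up to 2 called members that went against it. Pseudogenes, predicted genes and members of multigene families were counted but not named.

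Alternatives fixed before the data were examined were no filter, a filter above 7, array weights, only the arrays compared, quantile normalization, a common median, trended and robust eBayes, all single-symbol probe sets, the replicate number as a block, leaving out each array, and a fold threshold of 1.5. After the data were seen, 2 kinds were added. The first used array sets read from the first principal component of 998 probe sets taken as controls, which held 30.2% of their variance. No scan date or slide was used. The second tested each gene against the median difference of all tested genes instead of 0. The array labelled wild-type vehicle replicate 2, which stood apart, was also left out together with the array set block, and within set 1.

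Simulated data with 200 of 10452 genes changed tested the fit. For Ang II in wild-type cells it recovered 78.7% of genes changed by 1 (log2) and 99.2% of those changed by 2, with 4.92% false calls. In knockout cells it recovered 63.0% and 98.2%, and for 2-HOBA against Ang II 71.1% and 98.1%. A shift of 0.5 in the cell cycle list for Ang II in wild type was called in 20 of 20 runs. These rates cover no array sets or correlated genes.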

Results

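Transcript levels were measured on 28 arrays of splenic dendritic cells, the antigen-presenting cells of the spleen, to ask how oxidative stress affects their expression profile. Wild-type cells formed 4 groups: vehicle (n = 7), angiotensin II (Ang II, n = 4), Ang II with 2-hydroxybenzylamine (2-HOBA, n = 4), and Ang II with hydralazine and hydrochlorothiazide (Hyd/HCTZ, n = 6). Cells lacking NOX2 formed 2 groups, vehicle (n = 3) and Ang II (n = 4). Ang II is a peptide hormone that raises blood pressure, 2-HOBA is a scavenger of reactive dicarbonyls formed by lipid oxidation, hydralazine is a vasodilator and hydrochlorothiazide is a diuretic. The interquartile range of an array averaged 3.26 with Hyd/HCTZ and 2.53 to 2.72 in the other groups. The array labelled wild-type vehicle replicate 2 had a mean correlation of 0.852 with all other arrays and an interquartile range of 1.92. The first principal component of 998 unnamed probe sets, taken as controls from their identifiers alone, parted the arrays into 3 sets, chosen after the data were seen. The gap between sets 1 and 2 (-7.48 to -2.47) was narrower than that beside that array (-25.95 to -14.39). Set 1 held the 7 knockout arrays, wild-type vehicle replicates 1 to 3 and Ang II replicates 1 and 2. Set 2 held wild-type vehicle replicates 4 to 7, Ang II replicates 3 and 4 and the 4 arrays with 2-HOBA, and set 3 the 6 Hyd/HCTZ arrays.

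Cybb, which encodes NOX2, was read first in every sample. Its log2 level was 6.41 to 7.18 on the 7 knockout arrays and 8.35 to 9.75 on 20 of the 21 wild-type arrays. The remaining array, labelled wild-type vehicle replicate 2, had a Cybb level of 6.34 and so went against its label. Its level of Stx8, a syntaxin of endosomal membrane fusion, was 6.61, within the wild-type range of 5.56 to 6.90 and outside the knockout range of 3.02 to 3.84. Group means of Cybb were 8.74 to 9.40 in the 4 wild-type groups and 6.82 and 6.71 in the knockout groups. The array labelled replicate 2 was kept in its group and left out in turn in each comparison with that group.

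**Figure D1:**
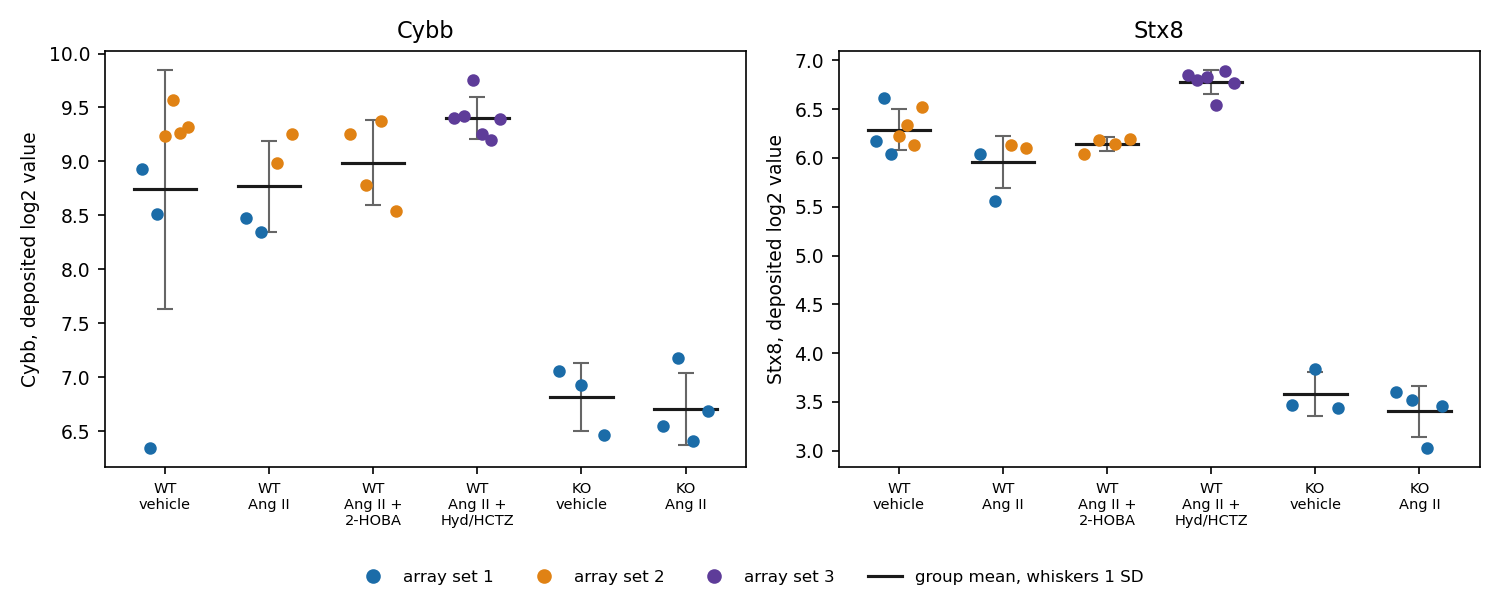
Log2 levels of Cybb and Stx8 (y axes, deposited RMA values) on each of the 28 arrays by group (x axes), with points for arrays and group means with whiskers of 1 SD. Cybb on the array labelled wild-type vehicle replicate 2 (6.34) lies among the knockout arrays (6.41 to 7.18), and Stx8 on the same array (6.61) lies among the wild-type arrays.

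The comparison of Ang II with vehicle in wild-type cells asked what Ang II changed. Markers of red pulp macrophages, the iron-recycling phagocytes of the spleen, lay lower with Ang II in 15 of 15 tested members, with a median difference of -0.68 (camera adjusted p = 1.98e-09; adjusted p = 0.675 with an estimated correlation). Mertk, a receptor for apoptotic cells, differed by -0.97 (6.04 ± 0.44, n = 4, against 7.01 ± 0.86, n = 7), Vcam1 by -0.90, C1qa by -0.96 and Cd163, the haptoglobin-haemoglobin receptor, by -0.71. Erythroid markers lay higher in 12 of 13 members, with a median of 0.43 (adjusted p = 8.84e-07; adjusted p = 0.675 with an estimated correlation). Rhd, a red cell surface protein, differed by 1.28, the carbonic anhydrase Car1 by 1.29 and Epb42, a membrane skeleton protein, by 0.72. The eicosanoid and aldehyde list had a median of -0.16 (adjusted p = 0.0487; adjusted p = 0.943 with an estimated correlation), with Alox5, which starts leukotriene synthesis, at -0.45 and the phospholipase Pla2g4a at -0.63.

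No single gene was called for Ang II in wild-type cells by limma, while 266 genes had an unadjusted p under 0.05. Adjusted over the list alone, 1 of 13 erythroid genes rose, and 1 of 12 cDC2 and 1 of 10 plasmacytoid genes fell. The smallest p values belonged to Ifi208, an interferon-inducible gene, at 0.97, to Pcyox1, a prenylcysteine oxidase, at -0.97 and to the lectin Clec10a at -1.05, on which all 4 Ang II arrays lay below all 7 vehicle arrays. Cybb (0.03, SE 0.36), Cyba (0.15) and Ncf1 (0.24), which encode oxidase subunits, did not differ past the test. The cytokine genes Il1b (-0.56) and Tnf (0.20), the costimulatory genes Cd80 (-0.24) and Cd86 (-0.19) and Hmox1, haem oxygenase 1 (-0.64), did not pass either. Cybb turned to -0.37 (adjusted p = 0.603) and Cyba to -0.15 (0.834) without the array labelled wild-type vehicle replicate 2.

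With the array set as a block, the red pulp median was -0.61 and the erythroid median 0.45, and within sets 1 and 2 they were -0.29 and -0.90, and 0.14 and 0.87. No list was called within set 1 (red pulp adjusted p = 0.221, erythroid 0.450 with camera's direction down). Within set 2 immediate early (-0.45), inflammatory (-0.40), cDC2 (-0.30) and plasmacytoid lists (-0.50) were also called lower and neutrophil (0.56) and B cell lists (0.25) higher, while the immediate early median was 0.32 within set 1. The eicosanoid call was lost with that block (adjusted p = 0.0620) and after quantile normalization (0.0649), and its median was 0.25 within set 1 and -0.44 within set 2. Within set 1 without the array labelled wild-type vehicle replicate 2, 2 arrays against 2, the medians were -0.42 for red pulp, -0.10 for erythroid and 0.05 for eicosanoid genes. It was also lost without that array (median -0.26, 0.0505), vehicle replicates 4 (-0.13, 0.107), 5 (-0.09, 0.0885), 6 (-0.10, 0.0896) or 7 (-0.10, 0.104), or Ang II replicates 2 (-0.08, 0.0520) or 3 (-0.19, 0.310). Without Ang II replicate 1 the erythroid median was 0.72. No gene was called within set 1 or set 2 by limma, with 1337 and 589 genes at an unadjusted p under 0.05. The glycolysis, cDC2 and shared dendritic cell lists, none of them called, disagreed in sign, as said below of lists whose median, mean and test had different signs.

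Adding 2-HOBA to Ang II in wild-type cells tested whether scavenging of reactive dicarbonyls altered the Ang II profile. Erythroid markers lay lower with 2-HOBA than with Ang II in 13 of 13 members, with a median of -0.74 (camera adjusted p = 8.13e-12; adjusted p = 0.296 with an estimated correlation), and adjusted over the list alone 6 of 13 fell. Rhd differed by -1.53 (4.13 ± 0.39 against 5.66 ± 0.84, n = 4 each) and Ermap by -0.74, with all 4 arrays with 2-HOBA below all 4 Ang II arrays for both. Slc4a1, the red cell anion exchanger, differed by -1.39 and Hemgn, a regulator of erythroid cells, by -1.01. Markers of B cells lay higher in 14 of 14 members, with a median of 0.63 (adjusted p = 9.56e-06; adjusted p = 0.849 with an estimated correlation). Among them Vpreb3 differed by 1.04, Fcrla by 0.95 and the antigen receptor component Cd79b by 0.73, and 2 of 14 rose when adjusted over the list alone.

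Neutrophil markers lay lower with 2-HOBA in 12 of 12 members, with a median of -0.60 (adjusted p = 1.70e-05), with the granule genes Ngp at -1.47 and Ltf at -1.09. Plasmacytoid markers lay higher in 10 of 10 members (median 0.42, adjusted p = 0.00126; adjusted p = 0.849 for both lists with an estimated correlation), with Cd300c at 0.77 and the chemokine receptor Ccr9 at 0.94. The cell cycle list had a median of -0.13 (adjusted p = 0.000330), with the proliferation marker Mki67 at -0.79 and the mitotic kinase Cdk1 at -0.54. The immediate early and heat shock list had a median of -0.24 (0.000358), with the stress-induced factor Atf3 at -1.14, and the red pulp list a median of -0.16 (0.0290), with C1qb at -0.53. Oxidative phosphorylation genes lay higher in 24 of 27 members (median 0.26, 0.00252), with the respiratory chain genes Uqcrb at 0.58 and Ndufv2 at 0.41. For these 4 lists the adjusted p was 0.984 with an estimated correlation.

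No gene was called between 2-HOBA and Ang II by limma, with 379 genes at an unadjusted p under 0.05. The smallest p values belonged to Incenp, a chromosomal passenger protein, at -0.96, Lzic at 0.79 and the protease Ctse at -1.81, each with complete separation of the 4 arrays of either group. Cybb differed by 0.22 (SE 0.41), Cyba by -0.02, Ncf1 by -0.05, Il1b by -0.16, Tnf by -0.28, Cd80 by 0.45, Cd86 by 0.32 and Hmox1 by -0.16, none past the test. Within set 2, with 2 Ang II arrays and all arrays with 2-HOBA, limma called 0 genes (237 unadjusted). Lists called there were erythroid (median -1.38), neutrophil (-0.55), plasmacytoid (0.19), cell cycle (-0.27), red pulp (-0.46), antioxidant (-0.17), cDC1 (-0.31) and platelet (0.20). B cell (0.05), immediate early and oxidative phosphorylation lists (-0.03 each) were not called. With the array set as a block, the medians were -1.06 for erythroid, -0.66 for neutrophil, -0.31 for cell cycle and -0.68 for red pulp markers, all still called. So was the B cell list (0.0482), its median turning to -0.0025. The plasmacytoid (0.201), immediate early (0.108) and oxidative phosphorylation (0.559) calls were lost.

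Several of these medians rested on single arrays. Without Ang II replicate 1 the oxidative phosphorylation call was lost (median 0.13, 0.238), the B cell median was 0.37 and the cell cycle median -0.20. Without Ang II replicate 2 the B cell median was 0.36. The immediate early call was lost without Ang II replicates 2 (-0.15, 0.0987) or 4 (-0.08, 0.0859) or 2-HOBA replicate 4 (-0.04, 0.360), and its median was -0.50 without Ang II replicate 3. The red pulp call was lost without Ang II replicate 4 (-0.02, 0.602) or 2-HOBA replicates 2 (-0.04, 0.496) or 4 (-0.06, 0.389), and its median was -0.27 to -0.38 without Ang II replicates 2 or 3 or 2-HOBA replicates 1 or 3. The cell cycle median was -0.06 without Ang II replicate 4 and -0.08 without 2-HOBA replicate 2, and the neutrophil median was -0.98 without Ang II replicate 4 and -0.95 without 2-HOBA replicate 4. The NADPH oxidase, chemokine, costimulation, glycolysis and plasma cell lists, not called, disagreed in sign.

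Ang II with Hyd/HCTZ was compared with Ang II alone in wild-type cells. The tested genes as a whole lay higher on these arrays, with a median difference of 0.32 that quantile normalization reduced to 0.02, so single genes are given relative to that shift. Tnfsf9, the costimulatory ligand 4-1BBL, rose at least 8.47-fold relative to the shift, with the signal threshold of 5 in place of the lower mean (8.40 ± 0.19, n = 6, against 3.59 ± 0.55, n = 4; fitted relative difference 4.49, SE 0.21, adjusted p = 2.78e-15). The heat shock gene Hspa1a rose 14.0-fold (9.60 ± 0.65 against 5.47 ± 0.42; 1.05e-10), the decoy interleukin 1 receptor Il1r2 by a log2 difference of at least 3.56, and the transcription factor genes Nr4a3, Crem and Egr2 8.24-fold, at least 5.01-fold and 7.72-fold. Il1b, a proinflammatory cytokine, rose 7.13-fold (10.80 ± 0.16 against 7.65 ± 0.79; 7.03e-07), and Cd86 and Cd80, which costimulate T cells, rose 5.39-fold (9.55 ± 0.13 against 6.80 ± 0.56; 3.22e-07) and 3.35-fold (9.00e-05). Cr2, a complement receptor of B cells, fell 14.2-fold (5.81 ± 0.26 against 9.31 ± 0.59; 7.73e-08), and Ebf1, a B cell transcription factor, fell 8.93-fold (5.00 ± 0.48 against 7.84 ± 0.09; 1.32e-08). For all of these genes the 6 Hyd/HCTZ arrays lay entirely above or below the 4 Ang II arrays.

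**Figure D2:**
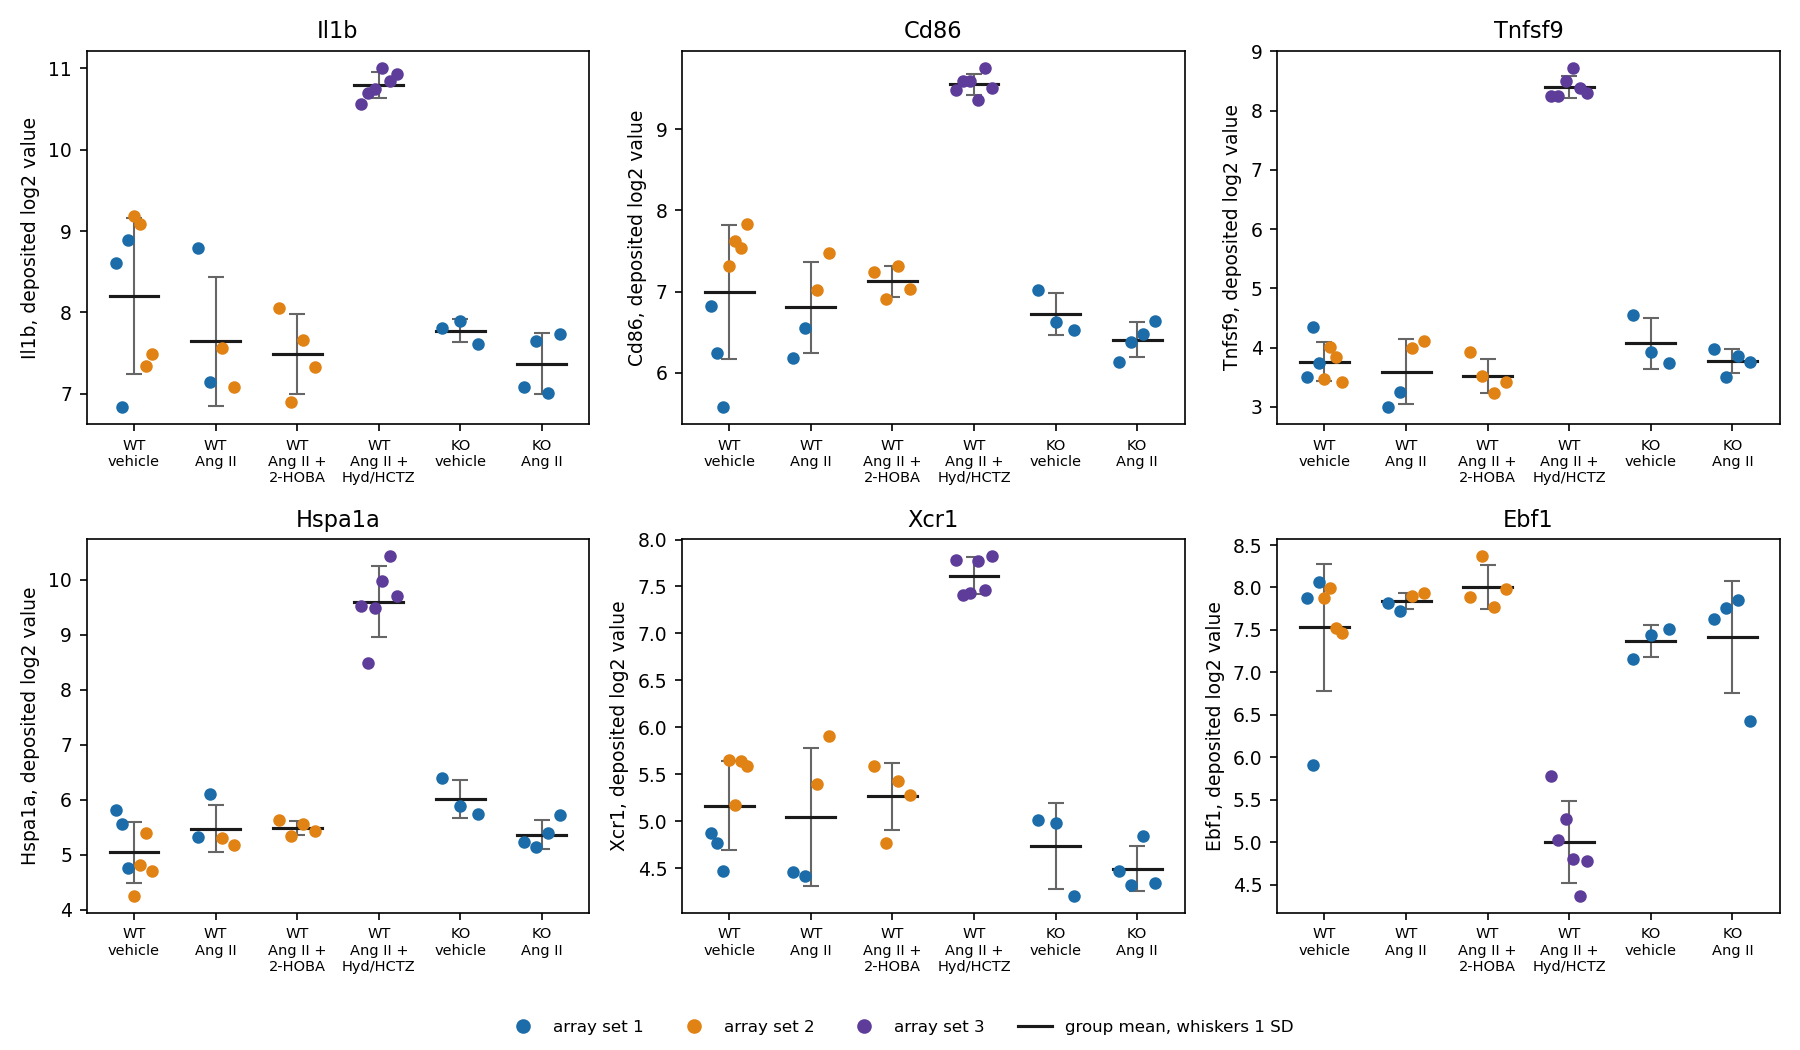
Log2 levels (y axes, deposited RMA values) of Il1b, Cd86, Tnfsf9, Hspa1a, Xcr1 and Ebf1 on each array by group (x axes), with points for arrays and group means with whiskers of 1 SD. The 6 Hyd/HCTZ arrays lie above the 4 wild-type Ang II arrays for the first 5 genes (Tnfsf9 8.40 against 3.59) and below them for Ebf1 (5.00 against 7.84).

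The Hyd/HCTZ comparison called 5503 genes by limma, 4261 higher and 1242 lower, with 6081 genes at an unadjusted p under 0.05. Relative to the shift it called 5083, 2472 higher and 2611 lower, of which 3714 were calls in the same direction without it. The share of higher calls was thus 77.4% as deposited, 48.6% relative to the shift, 57.1% after quantile normalization and 84.4% with a common array median. Other large rises relative to the shift were Snord14e, a small nucleolar RNA, at 12.4-fold and Grasp at 7.88-fold, and other large falls were the RNase P RNA Rpph1 at 12.6-fold, Trdn at 12.5-fold, the nucleolar RNA Rnu3a at 11.9-fold, n-R5s136 at no less than 7.63-fold, Mir6516 at 9.42-fold and the RNase MRP RNA Rmrp at 8.81-fold. Of the remaining genes fixed in advance, the oxidase subunit Cyba rose by 1.27 relative to the shift (adjusted p = 0.00150), while Cybb (0.32, 0.499), Ncf1 (0.36, 0.0964), Tnf (0.38, 0.123) and Hmox1 (0.52, 0.188) did not pass.

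Lists of activation and stress genes moved up with Hyd/HCTZ. Medians of list differences are as deposited, and counts of members are relative to the shift, with the count adjusted over the list alone after a slash where it differed. Immediate early and heat shock genes rose in 15/17 and fell in 1 of 26 members (median 1.27, camera adjusted p = 0.000105; adjusted p = 0.50004 with an estimated correlation), among them Dnajb1, a heat shock cochaperone, by 2.20 relative to the shift, against Jund at -0.88. Inflammatory genes rose in 10 and fell in 1 of 17 (0.98, 0.00155; adjusted p = 0.481 with an estimated correlation), with Il12b up by at least 1.78 and Il15 by at least 1.23, against Il12a at -0.32 or lower. Chemokine genes rose in 11 and fell in 2 of 16 (1.17, 0.00670), led by Ccl22, which attracts regulatory and type 2 helper T cells, up by 2.50. Costimulation genes rose in 7 of 14 (1.03, 0.00293; adjusted p = 0.445 for chemokine and costimulation genes with an estimated correlation), with the maturation marker Cd83 up by 2.00. Antioxidant genes rose in 7 of 17 (0.81, 0.00670), among them Nfe2l2, the master regulator of that response, up by 1.78, Sod2 by at least 1.07 and catalase (Cat) by 1.04. Eicosanoid genes rose in 7 of 14 (1.08, 0.0241; adjusted p = 0.528 for antioxidant and eicosanoid genes with an estimated correlation), with Ptgs2, the inducible cyclooxygenase, up by 2.72 and Alox5ap by 1.61.

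Respiratory and proliferation genes also moved up with Hyd/HCTZ. Oxidative phosphorylation genes rose in 21/22 of 27 members (median 1.40, camera adjusted p = 1.21e-06; adjusted p = 0.481 with an estimated correlation), with the complex I gene Ndufb5 up by 1.71 and cytochrome c (Cycs) by 1.70 relative to the shift. Cell cycle genes rose in 15 of 26 (0.93, 0.000804; adjusted p = 0.501 with an estimated correlation), with the spindle checkpoint kinase Bub1 up by at least 0.15 and Cdk1 by at least 0.99. Unfolded protein response genes rose in 7 and fell in 1 of 16 (0.71, 0.0299), with Herpud1 up by 1.82 and Pdia4 at -1.33. MHC class II genes rose in 5 and fell in 1 of 12 (0.83, 0.0434), with Ifi30 up by 1.80 and Marchf1, a ubiquitin ligase that removes MHC class II, at -0.67. MHC class I genes rose in 5 and fell in 1 of 14 (0.77, 0.0421), with the immunoproteasome gene Psmb9 up by 1.62. For these last 3 lists the adjusted p was 0.567 with an estimated correlation.

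Markers of dendritic cells, macrophages and monocytes lay higher with Hyd/HCTZ, and those of lymphocytes, neutrophils, erythroid cells and stroma lay lower. Type 1 dendritic cell markers rose in 12 of 13 members (median 1.46, camera adjusted p = 1.31e-05; adjusted p = 0.285 with an estimated correlation), with the chemokine receptor Xcr1 up by 2.25 relative to the shift (7.61 ± 0.20, n = 6, against 5.04 ± 0.73, n = 4) and Tlr3 by 1.93. Type 2 markers rose in 6/7 and fell in 1 of 12 (1.05, 0.0434; adjusted p = 0.567 with an estimated correlation), with Clec4a4 up by at least 1.83 and Dtx1 at -1.31, and shared dendritic cell genes rose in 7 of 10 (0.99, 0.00773; adjusted p = 0.501 with an estimated correlation), with Itgax up by 1.11. Red pulp macrophage markers rose in 9 of 15 (1.43, 0.00907), with C1qa up by 2.00 and Cd68 by 1.84, and monocyte markers rose in 6/8 and fell in 1 of 11 (1.29, 0.0421; adjusted p = 0.567 each with an estimated correlation), with Cd14 up by 2.85. B cell markers fell in 13 of 14 (-1.46, 1.63e-10; adjusted p = 0.285 with an estimated correlation), with the low-affinity IgE receptor Fcer2a at -3.14 and the B lineage factor Pax5 at -2.58. T cell markers fell in 13/14 of 15 (-0.89, 5.82e-08; adjusted p = 0.115 with an estimated correlation), with the receptor signalling gene Lat at -1.79. Erythroid markers fell in 11 of 13 (-1.27, 9.70e-07; adjusted p = 0.302 with an estimated correlation), with Alas2, which starts haem synthesis in red cells, at -2.39 or lower, and neutrophil markers fell in 8/9 of 12 (-1.13, 0.000518; adjusted p = 0.481 with an estimated correlation), with Ngp at -2.27 or lower. Stroma markers fell in 5/7 of 8 (-0.43, 0.00145; adjusted p = 0.115 with an estimated correlation), and NK cell markers fell in 6 and rose in 2 of 14 (-0.20, 0.0299; adjusted p = 0.567 with an estimated correlation), with Klra8 at -1.99 against Ccl5 at 0.94.

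Lists not called were NADPH oxidase (1 rose and 1 fell of 7, median 0.59, adjusted p = 0.523), interferon-stimulated genes (7 rose and 6 fell of 22, 0.48, 0.603), glycolysis (8 rose and 1 fell of 18, 0.63, 0.133), plasmacytoid markers (5 rose and 1/2 fell of 10, 1.00, 0.356), plasma cell markers (2 rose and 1 fell of 7, 0.21, 0.883) and platelet markers (1/0 rose and 1 fell of 8, 0.10, 0.380). Relative to the shift the plasma cell and platelet medians turned to -0.11 and -0.22, and the platelet list disagreed in sign. After quantile normalization the MHC class I (0.0946), unfolded protein response (0.111) and cDC2 (0.0745) calls were lost. The MHC class II call was lost without Ang II replicates 1 (0.0740) or 2 (0.0645) or Hyd/HCTZ replicate 4 (0.0676), MHC class I without Ang II replicate 1 (0.0591), cDC2 without Ang II replicate 3 (0.0898), monocyte without Ang II replicates 2 (0.0645) or 4 (0.0511), and NK cell without Ang II replicate 3 (-0.05, 0.182) or Hyd/HCTZ replicate 4 (-0.08, 0.0658). The neutrophil median was -0.74 without Ang II replicate 3, and the NK cell median -0.35 without Ang II replicates 1 or 2. All 6 Hyd/HCTZ arrays, and no others, formed array set 3, so array set and treatment cannot be told apart for any of these differences, and an array set block is no test of them.

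**Figure D3:**
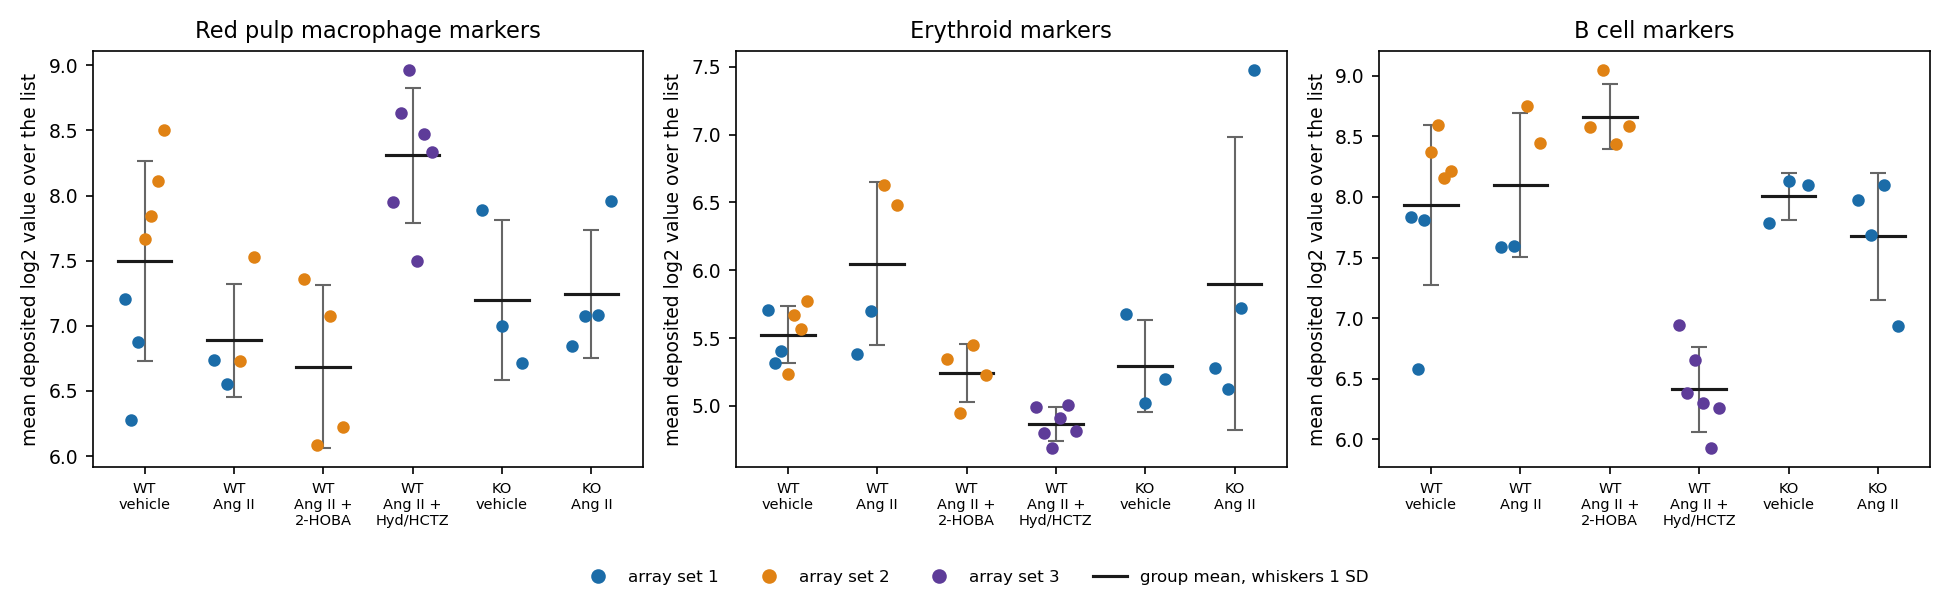
Mean log2 level (y axes) of the red pulp macrophage, erythroid and B cell marker lists on each array by group (x axes), with points for arrays and group means with whiskers of 1 SD. The B cell mean averages 6.41 on the Hyd/HCTZ arrays and 8.10 on the wild-type Ang II arrays, while the red pulp mean averages 8.31 and 6.89.

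Between the co-treatments, the 2-HOBA arrays were compared with the same 6 Hyd/HCTZ arrays, with a median shift of all tested genes of -0.25. Relative to that shift Tnfsf9 was lower with 2-HOBA by a log2 difference of at least 3.15 (fitted -4.63; 3.52 ± 0.29, n = 4, against 8.40 ± 0.19, n = 6; SE 0.21, adjusted p = 1.24e-15), Hspa1a by -3.86, Il1r2 by at least 3.63, Nr4a3 by -3.67, Ptgs2 by -3.35, Il1b by -3.06, Cd86 by -2.18, Cd80 by -1.36 and Cyba by -1.35. Cr2 was higher with 2-HOBA by 4.13, Fcer2a by 3.82, Cd55, a complement regulator, by at least 3.33, Ebf1 by 3.25 and Ms4a1, which encodes CD20, by 3.11. Limma called 4774 genes, 1016 higher with 2-HOBA and 3758 lower (5479 at an unadjusted p under 0.05), and relative to the shift 4631, 2202 higher and 2429 lower. The share of higher calls was 21.3% as deposited, 47.5% relative to the shift and 39.7% after quantile normalization. Tnf (-0.72, adjusted p = 0.00493) and Ncf1 (-0.48, 0.0326) also fell relative to the shift, and Hmox1 (-0.75, 0.0604) and Cybb (-0.16, 0.742) did not pass.

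Of the 28 lists, 20 were called between 2-HOBA and Hyd/HCTZ, each with an adjusted p of at least 0.117 with an estimated correlation. B cell markers lay higher with 2-HOBA in 14 of 14 members (median 2.01, camera adjusted p = 7.24e-16), T cell markers in 14 of 15 (0.72, 3.56e-07) and stroma markers in 8 of 8 (0.42, 0.00296). Immediate early genes (median -1.62, 3.51e-07), cell cycle genes (-1.09, 3.80e-06), cDC1 markers (-1.47, 5.73e-06), oxidative phosphorylation genes (-1.09, 4.00e-05), inflammatory genes (-1.26, 0.000191), red pulp markers (-1.69, 0.000759) and costimulation genes (-1.24, 0.00174) lay lower. So did antioxidant (-0.83), chemokine (-1.26), eicosanoid (-1.20), unfolded protein response (-0.71), cDC2 (-0.99), shared dendritic cell (-0.78) and monocyte genes (-1.22). NK cell (0.43, 0.00765), erythroid (0.24, 0.00784) and neutrophil markers (0.33, 0.0445) lay higher. The erythroid and neutrophil calls after quantile normalization (0.103 and 0.2201) were lost, and the neutrophil call without 2-HOBA replicates 1 (0.21, 0.0508) or 4 (0.06, 0.0943) or Hyd/HCTZ replicates 1 (0.24, 0.0700), 2 (0.25, 0.0578) or 5 (0.29, 0.0501). The neutrophil median was 0.56 and the NK cell median 0.26 without Hyd/HCTZ replicate 4, and the erythroid median was 0.13 without 2-HOBA replicate 3. No array set held both groups, so this comparison has no value within a set or with a set block, and the plasmacytoid list, not called, disagreed in sign.

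Against vehicle, Ang II with Hyd/HCTZ showed rises relative to a shift of 0.31 in Tnfsf9 by at least 3.09 (fitted 4.32; 8.40 ± 0.19, n = 6, against 3.76 ± 0.34, n = 7; adjusted p = 1.28e-16), Hspa1a by 4.24, Nr4a3 by 3.39, Crem by at least 2.33, the small GTPase Rrad by at least 2.54, Il1b by 2.28, Cd86 by 2.25, Xcr1 by 2.14 and Cycs by 2.01. Falls included Rpph1 (-3.65), Rnu3a (-3.33), Cr2 (-3.27), Rmrp (-3.10), Mir6516 (-3.06), Trdn (-3.04), Fcer2a (-3.01), Snord49b (-2.89) and Ebf1 (-2.84). Cd80 (1.52), Cyba (1.42), Ncf1 (0.61, adjusted p = 0.00166) and Tnf (0.58, 0.00594) rose, and Hmox1 (-0.12, 0.747) and Cybb (0.35, 0.371) did not pass. Limma called 5919 genes, 4537 higher and 1382 lower (6437 at an unadjusted p under 0.05), and relative to the shift 5467, 2645 higher and 2822 lower, so that higher calls made up 76.7% as deposited, 48.4% relative to the shift and 55.6% after quantile normalization.

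Called lists against vehicle numbered 15, each with an adjusted p of at least 0.0739 with an estimated correlation. They were led by T cell markers (median -1.03, camera adjusted p = 9.95e-11), B cell markers (-1.32, 9.95e-11), oxidative phosphorylation (1.35, 3.16e-07) and cDC1 markers (1.35, 1.58e-05). Costimulation (1.30), immediate early (1.19), inflammatory (1.10), chemokine (1.02), cell cycle (0.91), shared dendritic cell (0.87), unfolded protein response (0.68) and antioxidant genes (0.67) lay higher, and neutrophil (-0.88), erythroid (-0.57) and stroma markers (-0.39) lower. The unfolded protein response call was lost after quantile normalization (0.0647), and none was lost by leaving out a single array. The red pulp list, with a median of 0.74, was not called (0.318), and the plasma cell and platelet lists, not called, disagreed in sign.

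With Ang II and 2-HOBA against vehicle, red pulp markers lay lower in 15 of 15 members, with a median of -0.81 (camera adjusted p = 1.09e-13; adjusted p of at least 0.515 with an estimated correlation for this and every list of this comparison). Mertk differed by -1.42 (5.59 ± 0.95, n = 4, against 7.01 ± 0.86, n = 7) and Cd163 by -1.02, and adjusted over the list alone 6 of 15 fell. B cell markers lay higher in 14 of 14 members (median 0.67, 8.52e-10), with Vpreb3 at 1.01 and the follicular homing receptor Cxcr5 at 1.11, and 8 of 14 rose when adjusted over the list alone. Immediate early (-0.29, 8.22e-06), cell cycle (-0.20, 4.75e-05), T cell (-0.23, 0.000166), neutrophil (-0.57, 0.000150), eicosanoid (-0.14, 0.00223), erythroid (-0.34, 0.00426) and inflammatory lists (-0.08, 0.00824) lay lower, and oxidative phosphorylation (0.31, 0.000138) and NK cell lists (0.36, 0.0359) higher. Members with small p values were Dusp1, a phosphatase that ends MAP kinase signalling, at -0.95, the inflammasome sensor Nlrp3 at -0.89 and Alox5 at -0.96, and adjusted over the list alone 1 eicosanoid gene fell and 1 inflammatory gene rose and 1 fell.

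No gene was called between 2-HOBA and vehicle by limma, with 602 genes at an unadjusted p under 0.05. Alox5 (adjusted p = 0.205), Apba1, a synaptic adaptor (-0.70, 0.291), and Sowahc (-0.74, 0.291) had the smallest p values, and Hmox1 (-0.81), Il1b (-0.72), Cybb (0.25), Cyba (0.13), Ncf1 (0.19), Tnf (-0.08), Cd80 (0.22) and Cd86 (0.13) did not pass. Cybb (-0.15), Cyba (-0.17) and Cd80 (-0.11) turned without the array labelled wild-type vehicle replicate 2. Without wild-type vehicle replicate 7 Alox5 was called (-1.07, 0.0144). Within set 2 limma called 0 genes (1247 unadjusted). Lists called there were red pulp (median -1.41), B cell (0.30), immediate early (-0.51), T cell (-0.42), eicosanoid (-0.50) and inflammatory (-0.46). So were cell cycle (-0.29), antioxidant (-0.22), cDC2 (-0.32), monocyte (-0.54) and stroma lists (0.26). Neutrophil (-0.46), erythroid (-0.27), NK cell (-0.15) and oxidative phosphorylation lists (-0.08) were not called. With the array set as a block the red pulp and B cell medians were -1.26 and 0.32, and the oxidative phosphorylation (0.4996), neutrophil (0.0637) and NK cell (0.972) calls were lost.

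Single arrays weighed on the weaker of these lists. Without the array labelled wild-type vehicle replicate 2 the erythroid call was lost (-0.35, 0.0632), and the medians were -0.30 for inflammatory, -0.28 for eicosanoid, 0.13 for oxidative phosphorylation and 0.19 for NK cell genes. Without 2-HOBA replicate 4 the inflammatory (-0.07, 0.0787) and NK cell (0.22, 0.453) calls were lost and the immediate early median was -0.15. Without 2-HOBA replicate 2 the eicosanoid median turned to 0.01, the erythroid median was -0.18 and the cell cycle median -0.13. The immediate early median was -0.44 without 2-HOBA replicate 3 and the T cell median -0.35 without 2-HOBA replicate 1. The NK cell call was also lost without vehicle replicates 1 (0.26, 0.181), 3 (0.31, 0.0672) or 6 (0.38, 0.0790), and over the other arrays left out the inflammatory and eicosanoid medians ranged from -0.20 to -0.03 and from -0.24 to -0.08. The unfolded protein response, glycolysis, cDC1, plasma cell and platelet lists, not called, disagreed in sign.

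**Figure D4:**
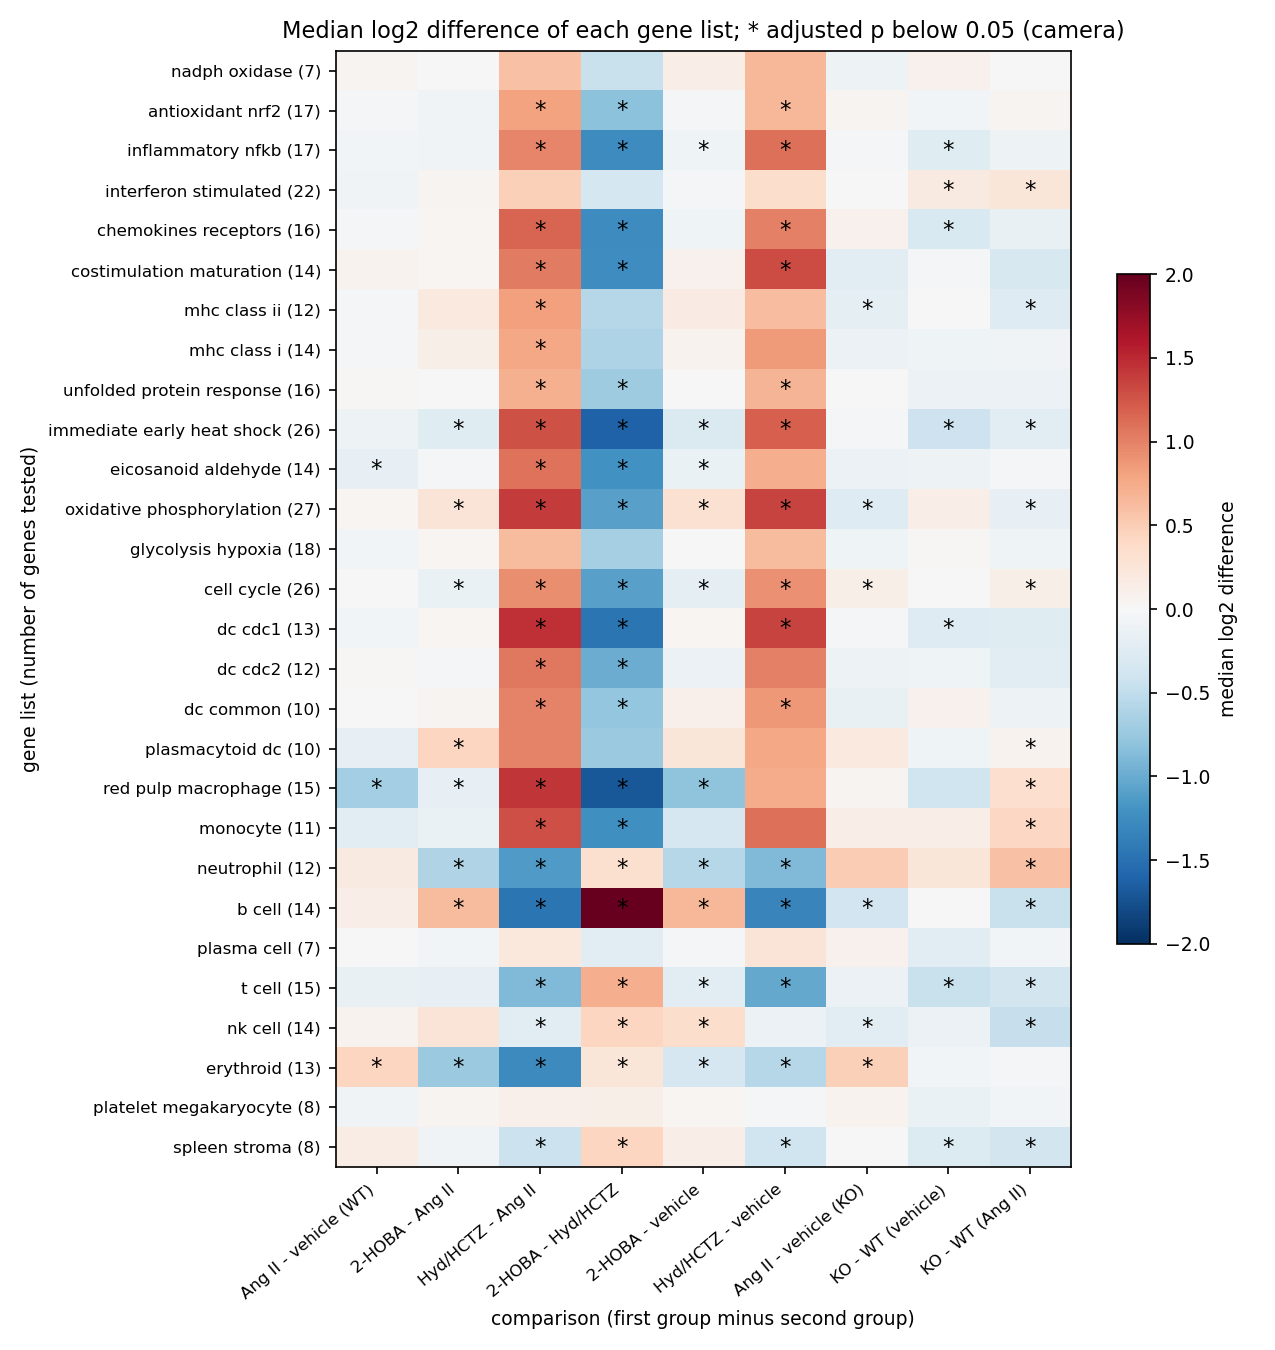
Median log2 difference (colour, from -2 to 2) of each of the 28 gene lists (vertical axis) in each of 9 comparisons (horizontal axis), with an asterisk where camera's adjusted p was below 0.05. The columns with Hyd/HCTZ hold the largest medians, such as -1.46 for B cell and 1.40 for oxidative phosphorylation genes against Ang II, and the erythroid median is 0.43 for Ang II against vehicle and -0.74 for 2-HOBA against Ang II.

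Ang II in knockout cells was compared with knockout vehicle to ask what Ang II changed without NOX2. Erythroid markers lay higher in 13 of 13 members, with a median of 0.47 (camera adjusted p = 4.84e-07; adjusted p = 0.998 with an estimated correlation for this and every called list of this comparison). Slc25a37, the mitochondrial iron importer, differed by 0.79 (7.76 ± 0.51, n = 4, against 6.97 ± 0.13, n = 3), with all 4 arrays above all 3, and Slc4a1 by 1.18. Oxidative phosphorylation genes lay lower in 26 of 27 members (median -0.27, 7.39e-05), with Cycs at -0.68. B cell (-0.39, 0.0149), MHC class II (-0.19, 0.0230) and NK cell lists (-0.23, 0.0241) also lay lower, with Cd79b at -0.60, H2-Ob at -0.55 and Nkg7 at -0.51, and the cell cycle list higher (0.11, 0.0230), with Bub1 at 0.59. No gene was called by limma (296 at an unadjusted p under 0.05), and the smallest p belonged to Smim8 (-0.83, adjusted p = 0.154), Otud1, a deubiquitinase (-0.93), and Tsr2 (-0.75), each lower on all 4 Ang II arrays than on all 3 vehicle arrays. Cybb (-0.11), Cyba (-0.28), Ncf1 (0.07), Il1b (-0.40), Tnf (-0.02), Cd80 (-0.25), Cd86 (-0.31) and Hmox1 (0.25) did not pass.

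The erythroid difference in knockout cells rested on Ang II replicate 4, whose erythroid list mean was 7.48. Without it the median was 0.13 (adjusted p = 0.622), and the cell cycle median turned to -0.09 (0.424) and the B cell (-0.17, 0.793), NK cell (-0.14, 0.424) and MHC class II (-0.20, 0.121) calls were lost. Without Ang II replicate 2 the oxidative phosphorylation (-0.11, 0.180) and MHC class II (-0.19, 0.169) calls were lost. Without Ang II replicate 3 the NK cell call (0.0812). Without vehicle replicate 1 the MHC class II call was lost (-0.11, 0.139). Without vehicle replicate 2 the B cell (-0.31, 0.156), cell cycle (0.04, 0.544) and NK cell (-0.16, 0.414) calls. Without vehicle replicate 3 the B cell (0.232), cell cycle (0.178), NK cell (0.0566) and MHC class II (0.0501) calls. With the call kept, the erythroid median reached 0.78, the cell cycle median 0.26 and the oxidative phosphorylation median -0.17. All 7 knockout arrays lay in array set 1. The inflammatory, chemokine, cDC1, plasma cell and stroma lists, not called, disagreed in sign.

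Knockout and wild-type cells were compared under vehicle to ask what the loss of NOX2 changed without Ang II. Stx8 fell by at least 1.29 on the log2 scale, with the threshold of 5 in place of the lower mean (6.29 ± 0.21, n = 7, against 3.58 ± 0.22, n = 3; fitted difference -2.71, SE 0.16, adjusted p = 1.02e-12), with all 3 knockout arrays below all 7 wild-type arrays, and the difference was -2.70 within set 1. Cybb itself differed by -1.92 (6.82 ± 0.31 against 8.74 ± 1.11, adjusted p = 0.207). Without the array labelled wild-type vehicle replicate 2 it differed by -2.32 (adjusted p = 1.98e-07). Within set 1 Cybb differed by -1.11 (0.0656). Cxcl2 was at 4.05 ± 0.35 in knockout and 7.07 ± 1.77 in wild-type cells (-3.02, 0.295), with all 3 arrays below all 7. Within set 1 it was at -2.73 (0.0400), inexact as its knockout level was below 5. The oxidase subunits Cyba (0.64) and Ncf1 (0.25) did not pass in the pooled fit, and within set 1, 3 arrays against 3, they differed by 1.32 (0.0211) and 0.63 (0.0469). Within set 1 without that array, 3 arrays against 2, neither passed (0.75, 0.164 and 0.47, 0.223), Cybb was at -1.91 (6.17e-05) and Cxcl2 at -3.48 (0.0425). Il1b (-0.43), Tnf (0.11), Cd80 (-0.03), Cd86 (-0.27) and Hmox1 (-0.40) did not pass.

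T cell markers lay lower in knockout vehicle cells in 15 of 15 members, with a median of -0.44 (camera adjusted p = 6.87e-06; adjusted p = 0.413 with an estimated correlation), with the T cell receptor component Cd3e at -0.90 and Lat at -0.61, and 2 of 15 fell when adjusted over the list alone. Immediate early genes had a median of -0.42 (0.000164; adjusted p = 0.885 with an estimated correlation), with Egr1 at -0.89 and Fosb at -1.46. Chemokine (-0.31, 0.00836; adjusted p = 0.697 with an estimated correlation), cDC1 (-0.25, 0.0107), inflammatory (-0.25, 0.0127) and stroma lists (-0.27, 0.0287; adjusted p = 0.413 with an estimated correlation) lay lower and interferon-stimulated genes higher (0.18, 0.0287), with an adjusted p of 0.885 with an estimated correlation for the cDC1, inflammatory and interferon lists. Tnfaip3, a brake on NF-κB signalling, was at -1.38, Cd36 at -0.68, the stromal chemokine Cxcl13 at -0.85, and the antiviral genes Zbp1 and Oas2 at 0.59 and 0.51. Adjusted over the list alone, 2 chemokine genes, 1 inflammatory and 1 NADPH oxidase gene fell, and 1 monocyte gene rose and 1 fell.

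Limma called 1 gene between the genotypes under vehicle, Stx8, with 657 at an unadjusted p under 0.05. Without the array labelled wild-type vehicle replicate 2 it called 68, without wild-type vehicle replicate 6 it called 2, and within set 1 it called 498, 422 higher and 76 lower, but 71, 44 higher and 27 lower, without the array labelled replicate 2. Within set 1 the medians were -0.17 for T cell, -0.19 for immediate early, 0.14 for inflammatory, 0.54 for interferon, -0.61 for stroma, -0.11 for chemokine and -0.01 for cDC1 genes (-0.28, -0.42, -0.05, 0.17, -0.48, -0.22 and 0.03 without it), and with the array set as a block the first 5 were -0.26, -0.37, -0.08, 0.36 and -0.57. Called only within set 1 were oxidative phosphorylation (0.57, adjusted p = 0.000108; 0.28, 0.000535 without that array), MHC class II (0.42), shared dendritic cell (0.39), plasmacytoid (0.68) and B cell lists (0.54), higher, and erythroid (-0.21) and platelet lists (-0.14), lower. Of these only oxidative phosphorylation was called without that array, where the unfolded protein response list (-0.21) was called too. The block ended the chemokine (0.0528), cDC1 (0.378) and inflammatory (0.103) calls. Over both sets without that array the chemokine (-0.36, 0.0893), cDC1 (-0.36, 0.194), interferon (0.07, 0.194) and stroma (-0.24, 0.406) calls were lost and the inflammatory median was -0.46. Array weights ended the immediate early (0.0863), chemokine (0.351) and interferon (0.274) calls and turned camera's direction for the stroma list (0.931). Without knockout replicate 1 the T cell (-0.24, 0.0509), interferon (0.17, 0.0609) and stroma (-0.28, 0.125) calls were lost and the cDC1 median was -0.42. The stroma call was lost without knockout replicate 2 (0.0608) or wild-type vehicle replicate 1 (0.0923), and the cDC1 (-0.15) and interferon (0.13) calls without knockout replicate 3 (0.141 each). Without wild-type vehicle replicate 3 the interferon (0.09) and stroma (-0.25) calls (0.0603 each) were lost. The NADPH oxidase, costimulation, MHC class II, cell cycle, cDC2 and plasmacytoid lists, not called, disagreed in sign.

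Under Ang II, 5 genes were called between the genotypes by limma (714 at an unadjusted p under 0.05), and all 4 knockout arrays lay beyond all 4 wild-type arrays for each. Stx8 fell by at least 0.96 (3.40 ± 0.26 against 5.96 ± 0.27, n = 4 each; fitted -2.55, SE 0.16, adjusted p = 9.64e-12), Coch, which encodes the extracellular protein cochlin, by at least 2.22 (4.91 ± 0.23 against 7.22 ± 0.40; 0.0209), Cybb by 2.06 (6.71 ± 0.33 against 8.77 ± 0.43; 0.0452) and the chaperone clusterin (Clu) by 1.32 (5.42 ± 0.14 against 6.74 ± 0.33; 0.0334). Apobr, a receptor for triglyceride-rich lipoproteins, rose by 0.85 (7.30 ± 0.15 against 6.46 ± 0.09; 0.0209). Within set 1, 4 arrays against 2, Stx8 was at -2.40, Coch at -2.58, Cybb at -1.71 (0.0913) and Apobr at 0.82 (0.0777). Of these calls only Stx8 remained with each of the 8 arrays left out in turn. Cybb was lost in all 8 runs (-1.90 to -2.22, adjusted p of 0.0625 to 0.152), with a common array median (0.0884) and the array set block (-1.48, 0.0502). The shared spread of these fits included the array labelled wild-type vehicle replicate 2. Without it the block fit called Cybb (-1.73, 9.86e-06). Apobr was kept only without knockout replicate 1, Clu only without wild-type replicate 4 and Coch only without either of these (otherwise 0.0625 to 0.111, 0.0590 to 0.133 and 0.0600 to 0.0898). With array weights these 3 were lost (0.151, 0.208 and 0.207). Cyba (0.20), Ncf1 (0.08), Il1b (-0.28), Tnf (-0.11), Cd80 (-0.04), Cd86 (-0.40) and Hmox1 (0.49) did not pass.

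Stroma markers lay lower in knockout Ang II cells in 8 of 8 members, with a median of -0.37 (camera adjusted p = 0.000933; adjusted p = 0.0852 with an estimated correlation), and 3 of 8 fell when adjusted over the list alone, among them Cxcl13 at -1.18 and the T zone chemokine Ccl19 at -0.91. T cell markers lay lower in 14 of 15 (median -0.37, 2.62e-05; adjusted p = 0.337 with an estimated correlation), with Cd28 at -0.80 and Lat at -0.64. NK cell markers lay lower in 14 of 14 (-0.46, 3.02e-05; adjusted p = 0.722 with an estimated correlation), with Nkg7 at -1.15 and Ccl5 at -0.84, and 2 fell when adjusted over the list alone. Interferon-stimulated genes lay higher (0.24, 0.00322; adjusted p = 0.722 with an estimated correlation), and 2 of 22 rose when adjusted over the list alone, with the antiviral synthetases Oas3 at 0.75 and Oas2 at 0.79. Immediate early (-0.20, 0.00322), B cell (-0.44, 0.00686), MHC class II (-0.25, 0.0470) and oxidative phosphorylation lists (-0.17, 0.0470) lay lower, and red pulp (0.34, 0.00496), monocyte (0.41, 0.00959), cell cycle (0.12, 0.0122), plasmacytoid (0.07, 0.0468) and neutrophil lists (0.58, 0.0470) higher, and no call held with an estimated correlation. Examples were Nr4a3 at -1.15, Mertk at 1.10, the angiotensin-converting enzyme Ace at 1.46 and Fcgr4 at 1.18 among monocyte markers, Cd300c at 0.77 and Ltf at 1.44. Adjusted over the list alone, 6 chemokine genes fell and 1 rose, 2 immediate early genes and 1 NADPH oxidase gene fell, 2 monocyte genes rose and 1 fell, and 1 cDC2 gene rose.

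Within set 1 limma called 10 genes under Ang II, 4 higher and 6 lower in knockout cells. Lists called there were T cell (median -0.46), stroma (-0.55), interferon (0.33), immediate early (-0.47) and red pulp (0.55). So were monocyte (0.74), cell cycle (0.23), plasmacytoid (0.51) and erythroid lists (0.43). NK cell (-0.13), B cell (0.03), MHC class II (0.11), oxidative phosphorylation (0.12) and neutrophil lists (0.62) were not called. With the array set as a block the medians were -0.38 for T cell, -0.56 for stroma, 0.49 for interferon, 0.83 for red pulp and 0.76 for plasmacytoid genes, all called, and the NK cell (-0.04, 0.0737), B cell (0.755), MHC class II (0.08, 0.830), oxidative phosphorylation (0.20, 0.414), cell cycle (0.0594) and neutrophil (0.830) calls were lost. Quantile normalization ended the MHC class II, oxidative phosphorylation (0.0769 each) and neutrophil (0.156) calls. Without knockout replicate 4 the red pulp (0.13, 0.317), B cell (-0.21, 0.406), monocyte (0.20, 0.287), neutrophil (0.02, 0.918), MHC class II (-0.19, 0.0678) and cell cycle (-0.10, 0.406) calls were lost. Without wild-type replicate 2 the immediate early (-0.13, 0.263), red pulp (0.27, 0.0503), monocyte (0.29, 0.106), neutrophil (0.40, 0.181) and plasmacytoid (0.06, 0.181) calls. Without wild-type replicate 3 the B cell (-0.32, 0.293), MHC class II (-0.13, 0.124) and oxidative phosphorylation (-0.05, 0.973) calls were lost, the NK cell median was -0.26 and the immediate early median -0.44. Without wild-type replicate 4 the immediate early (-0.13, 0.0575), MHC class II (-0.16, 0.352), oxidative phosphorylation (-0.15, 0.0794) and neutrophil (0.36, 0.528) calls. Without wild-type replicate 1 the cell cycle (0.01, 0.101) and plasmacytoid (-0.01, 0.146) calls were lost. Without knockout replicate 1 the plasmacytoid (0.12, 0.0821) and MHC class II (-0.26, 0.0505) calls. Without knockout replicate 2 the plasmacytoid (0.15, 0.0510), MHC class II (-0.16, 0.194), oxidative phosphorylation (-0.05, 0.961) and neutrophil (0.57, 0.0974) calls. Without knockout replicate 3 the plasmacytoid call (0.108). With the call kept, single arrays moved medians as far as 0.93 for neutrophil, 0.52 for red pulp, -0.33 for oxidative phosphorylation, 0.25 for cell cycle and 0.28 for plasmacytoid genes. The NADPH oxidase and eicosanoid lists, not called, disagreed in sign.

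Whether the Ang II difference itself differed between genotypes was tested as an interaction. Red pulp markers had a more positive Ang II difference in knockout cells, with a median of 0.77 (camera adjusted p = 0.000101; adjusted p = 0.877 with an estimated correlation for this and every called list of the interaction), with Mertk at 1.29 and Vcam1 at 1.20. Oxidative phosphorylation (-0.28, 0.000466), B cell (-0.46, 0.00178) and NK cell lists (-0.38, 0.0137) had more negative ones, with Cycs at -0.98. No gene was called by limma (257 at an unadjusted p under 0.05), and Prap1 (-1.15), Tsr2 (-0.92) and Smim8 (-0.78) had the smallest p values, with Cybb at -0.14 (0.26 without the array labelled wild-type vehicle replicate 2) and Hmox1 at 0.89. With the array set as a block the medians were 0.70, -0.37, -0.54 and -0.43. The red pulp median was 1.16 without knockout vehicle replicate 1, 0.50 without knockout vehicle replicate 3 and 0.38 without knockout Ang II replicate 4. The oxidative phosphorylation call was lost without knockout Ang II replicate 2 (-0.16, 0.118) or wild-type Ang II replicate 3 (-0.10, 0.132), the B cell call without knockout Ang II replicate 4 (0.280) or wild-type Ang II replicate 3 (0.126; -0.28 each), and the NK cell call without those 2 arrays (-0.22, 0.225 and -0.05, 0.413), knockout vehicle replicate 2 (-0.22, 0.171) or wild-type vehicle replicate 1 (0.0828). Without the array labelled replicate 2 these 3 medians were -0.11, -0.21 and -0.22, and the oxidative phosphorylation median was -0.16 without knockout vehicle replicate 2 and -0.45 without knockout vehicle replicate 3 or wild-type Ang II replicate 1. The T cell list, not called, disagreed in sign.

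Across 10452 genes, the Ang II differences of the genotypes had a Pearson correlation of 0.0519 and a Spearman correlation of 0.0392; genes are not independent replicates. Of the genes at an unadjusted p under 0.05 in both, 3 were higher in both against 1.20 expected from independent lists, 5 lower in both against 2.71 expected, and 6 opposite. The change with 2-HOBA against Ang II correlated at -0.381 with the change by Ang II against vehicle, and that with Hyd/HCTZ at -0.372. The Ang II arrays enter both sides of these correlations, and unchanged groups simulated around the same arrays gave -0.533 (-0.860 to 0.106) and -0.574 (-0.896 to 0.0753) over 100 draws. With the Ang II arrays split between the sides, the mean over 6 splits was 0.148 (-0.0839 to 0.516) for 2-HOBA and -0.112 (-0.268 to 0.258) for Hyd/HCTZ.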

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

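Tests chosen only after the results were seen were those on the control probe sets, on marker lists after quantile normalization, on the genes nearest to Cybb, within set 1 without 1 array, and the 3 tests on erythroid genes. The counts over other splits of the arrays and the share of calls left after quantile normalization, and, once the array sets and the fall of Stx8 had been seen, the Stx8 tests within set 1 and on its nearest genes, were written down before their own values were seen.

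Single arrays stood far from the rest of their group in 20 of 190 tests, made on 38 measures in 5 groups, where about 1 in 20 is expected by chance. Of these, 10 lay on the array labelled wild-type vehicle replicate 2, whose mean correlation with the other arrays was 0.852 (other arrays of the group 0.935 to 0.956). Its Cybb level was 6.34 (others 8.51 to 9.57) and its Cd80 level 3.79 (5.69 to 6.66). Its list means were 6.88 for NADPH oxidase (7.60 to 8.06), 5.90 for inflammatory (6.57 to 7.08), 7.29 for MHC class I (8.04 to 8.59), 6.20 for unfolded protein response (7.26 to 7.62), 6.46 for monocyte (7.41 to 8.10), 6.58 for B cell (7.81 to 8.59) and 5.91 for plasma cell genes (6.69 to 7.07). Hyd/HCTZ replicate 4 had list means of 8.42 for antioxidant (others 8.73 to 8.89), 7.46 for inflammatory (7.838 to 7.996), 7.63 for chemokine (8.03 to 8.20), 7.32 for costimulation (7.72 to 7.89) and 6.76 for glycolysis genes (7.08 to 7.24), and a Tnf level of 6.74 (7.21 to 7.40). Among wild-type Ang II arrays, replicate 3 had an immediate early mean of 6.62 (others 7.80 to 7.99), replicate 2 a monocyte mean of 6.99 (7.40 to 7.47) and replicate 1 a plasma cell mean of 6.40 (6.73 to 6.76). Cd80 on 2-HOBA replicate 2 was 5.12 (others 6.18 to 6.37).

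The Ang II difference was tested between genotypes for 28 lists, and 4 differed with the preset correlation and none with an estimated one. Their medians, knockout minus wild type, were -0.28 for oxidative phosphorylation, 0.77 for red pulp macrophage, -0.46 for B cell and -0.38 for NK cell genes. Leaving out 1 array ended the oxidative phosphorylation and B cell calls in 2 runs each (adjusted p of 0.118 to 0.280) and the NK cell call in 4 (0.0828 to 0.413). Among 5893 probe sets with no symbol or several, which no comparison used, limma called 2451 between Hyd/HCTZ and Ang II, 2041 between 2-HOBA and Hyd/HCTZ, 2776 between Hyd/HCTZ and vehicle, 1 between 2-HOBA and Ang II, 3 between 2-HOBA and vehicle, 9 between genotypes under vehicle and 13 under Ang II. Among the 998 probe sets taken as controls, 163 were called between 2-HOBA and Hyd/HCTZ, 253 between Hyd/HCTZ and vehicle and 1 between genotypes under vehicle.

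The Hyd/HCTZ arrays differed from the other wild-type arrays, with 5503 genes called against Ang II. Of these calls 64.0% remained in the same direction after quantile normalization, which argues against the wider spread of values on these arrays as the whole cause. After quantile normalization the red pulp macrophage mean was higher by 1.02 (7.97 ± 0.47 against 6.96 ± 0.39; exact permutation p = 0.0143). The B and T cell means differed by -2.01 and -0.99 (0.00476 each, the smallest possible). The unknown gate may keep macrophages, so a purer preparation stays open. Of the 998 probe sets taken as controls 187 were called between Hyd/HCTZ and Ang II arrays. Since all Hyd/HCTZ arrays and no others formed set 3, separate processing of these arrays cannot be told apart from the treatment. An effect of Hyd/HCTZ on the cells stays open, as does a mixture of changes in cell types.

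Stx8 was lower in cells from knockout mice in both treatments. Within array set 1 the differences were -2.70 under vehicle and -2.40 under Ang II, which argues against the array set. Stx8 lies on another chromosome than Cybb, which argues against a segment carried along with the Cybb mutation. The 50 tested genes nearest to Cybb thus could not include Stx8. Of the 10 tested genes nearest to Stx8, 0 passed limma's limit of 0.01 in both genotype comparisons. Gas7 passed it under vehicle alone, at 0.51 there and 0.13 under Ang II. Since a segment might change the level of no other gene in it, a chromosome segment around Stx8 that differs between the mice cannot be told apart from an effect of the loss of NOX2. The genotype effect itself stays open and was not tested further.

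Erythroid markers lay higher in wild-type Ang II arrays (median 0.43) and lower with 2-HOBA (-0.74). Within array set 2 the medians were 0.87 and -1.38, which argues against the array set as the cause, though within set 1 the Ang II median was 0.14, and -0.10 without the array labelled wild-type vehicle replicate 2. The unadjusted exact permutation p of the list mean was 0.0606 for Ang II and 0.0571 for 2-HOBA (adjusted at least 0.99 and 0.8), so chance could account for both. The 4 adult haemoglobin probe sets had a median difference of 0.0342 between Ang II and vehicle. Their levels averaged 11.6 to 12.3, but they differed by 0.42 to 0.69 for Ang II in knockout cells, so they can move at this level. Since a high baseline can still hide a smaller share, more red cell precursors among the isolated cells could not be decided. A treatment effect on these also stays open, as untested.

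Other splits of the same arrays were counted for each comparison, the real split included. Hyd/HCTZ against Ang II called 5503 genes, 2-HOBA against Hyd/HCTZ 4774 and Hyd/HCTZ against vehicle 5919. Of 100 splits from 210, 210 and 1716 possible, only the real split called as many (highest others 2666, 2288 and 5186). Chance is thus unlikely, but the array set is not excluded. A count of 0 tests nothing, since every split calls as many. For 2-HOBA against Ang II, Ang II in knockout cells and the interaction (0 genes each) the highest others called 25, 3 and 198. These comparisons had 35, 35 and 100 splits, and 379, 296 and 257 genes at an unadjusted p under 0.05. Chance cannot be excluded for the counts between genotypes, 5 under Ang II and 1 under vehicle. As many were called by 3 of 35 splits (highest other 11) and 16 of 100. The count under vehicle does not bear on Stx8 itself, whose adjusted p was 1.02e-12 with all 3 knockout arrays below all 7.

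Some splits called many more genes than the real ones, which points to structure among the samples, and in the first 2 cases below they followed the array sets. For Ang II against vehicle in wild-type cells (0 genes, 266 unadjusted, 100 splits) the highest other split called 4164. It had 4 arrays of set 1 on 1 side and 6 of set 2 and 1 of set 1 on the other. For 2-HOBA against vehicle (0 genes, 602 unadjusted, 100 splits) the highest called 4188. It set wild-type vehicle replicates 1 to 3 and 2-HOBA replicate 4 against 7 arrays of set 2. For the genotypes under vehicle the highest called 3622, with set 1 on both sides. It set wild-type vehicle replicates 1 to 3 against replicates 4 to 7 and the knockout arrays. Blocking on the array set, limma called 0, 0 and 144 genes in these 3 comparisons. Within set 1 it called 498 between genotypes under vehicle, and 71 without the array labelled replicate 2.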

How the results depend on the processing

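Tests with the array set as a block, alone or without the array labelled wild-type vehicle replicate 2, and tests against the median shift were chosen only after the results were seen. The array set block tests nothing for Hyd/HCTZ, whose arrays alone formed set 3. Of counts and correlations, 291 stayed within the bounds set for them and 43 moved; of the medians of 11 of the 109 called lists 120 kept their call, 22 lost it and 1 turned; of named genes 810 kept their side of the threshold, 11 lost it and 16 gained it. The number of calls for Hyd/HCTZ depends on signal over background through the genes tested: against Ang II it was 5503, 8761 without a filter and 2552 above a log2 value of 7 in at least 3 arrays; against vehicle 5919, 10334 and 2679; and between 2-HOBA and Hyd/HCTZ 4774 and 2262 with the stricter filter. The stricter filter left 0 genes called between genotypes under vehicle (limma; Stx8 was not tested there). The reversal restricted to called genes gave no value, since 0 were called. Replicate numbers paired the arrays in no comparison; with them as a block limma called 2 genes between genotypes under vehicle and 11 under Ang II, and the block changed no other count by over 1.5 times. It ended the list calls for red pulp in the interaction (adjusted p = 0.0670), eicosanoid for Ang II in wild type (0.270), neutrophil for 2-HOBA against Hyd/HCTZ (0.0721), inflammatory and eicosanoid for 2-HOBA against vehicle (0.0862 and 0.0813), cell cycle for Ang II in knockout (0.157) and cDC1 between genotypes under vehicle (0.203).

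With an unadjusted p below 0.05 and a fold of at least 1.5 in place of the adjusted p, the counts were 60 for Ang II in wild type, 131 for 2-HOBA against Ang II, 199 for 2-HOBA against vehicle, 103 for Ang II in knockout, 247 and 339 between genotypes under vehicle and Ang II, and 189 for the interaction; no correction for the number of genes is made there. Array weights gave 108 for 2-HOBA against vehicle, 1 for Ang II in knockout, 1437 (190 higher, 1247 lower) between genotypes under vehicle and 3 under Ang II; the array labelled wild-type vehicle replicate 2 had a weight of 0.0617. Beside the genotypes under vehicle, weights ended the list calls for oxidative phosphorylation (0.0747), neutrophil (0.915), NK cell and erythroid (0.182 each) for 2-HOBA against vehicle, MHC class II (0.0546), cell cycle (0.261) and B cell (0.191) for Ang II in knockout, cell cycle (0.412), red pulp (0.112) and neutrophil (0.141) between genotypes under Ang II, and cDC2 (0.0555) for Hyd/HCTZ against Ang II. Quantile normalization gave 1 for Ang II in knockout, 2 and 13 between genotypes under vehicle and Ang II. Blocking on the array set, the counts between genotypes were 144 and 40. The B cell median of 2-HOBA against Ang II turned from 0.63 to -0.0025, the list still called higher (0.0482). With that block and without that array, the counts were 30 for 2-HOBA against vehicle, 1 for Ang II in knockout, and 41 and 82 between genotypes. A fit of the compared arrays alone called 14 between genotypes under Ang II. An estimated correlation between genes left 0 of 109 list calls; the estimate widens each test. Fry called 75 lists, of which 53 were among the 109, 52 of them in the 3 comparisons with Hyd/HCTZ. Apart from the filters, the unadjusted p and the estimated correlation, the cause was not tested.

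Leaving out 1 array at a time gave 0 to 1 genes for 2-HOBA against Ang II (1 without wild-type Ang II replicate 3), 0 to 1 for 2-HOBA against vehicle (1 without vehicle replicates 2 or 7), 1 to 68 between genotypes under vehicle (68 without the array labelled wild-type vehicle replicate 2) and 1 to 3 under Ang II. It gave 4585 to 5521 for Hyd/HCTZ against Ang II, 3973 to 4774 for 2-HOBA against Hyd/HCTZ, 5305 to 6257 for Hyd/HCTZ against vehicle, and 98 to 115 list calls, where a call was ended 98 times in all. The reversal correlations ranged from -0.642 to -0.238 for 2-HOBA and from -0.497 to -0.244 for Hyd/HCTZ, and the correlation of Ang II differences between genotypes from -0.0371 (without wild-type Ang II replicate 1) to 0.155. Named genes gained were Cxcl2 between genotypes under vehicle (-3.32, adjusted p = 0.0194, without that array; over the alternatives that gained it 0.0136 to 0.0350), Tnfaip3 there (-1.57, 0.0285, without that array), Cybb there (-2.32, 1.98e-07, without that array; quantile normalization -1.86, 0.0125), Alox5 (-0.72, 0.0328), Apba1 (-0.75, 0.0163) and Sowahc (-0.71, 0.0222) for 2-HOBA against vehicle with array weights, and Smim8 for Ang II in knockout (-0.93, 0.0241, after quantile normalization).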

Other observations

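The array set block and gene families by name were tests chosen after the results were seen. With that block, without the array labelled wild-type vehicle replicate 2, limma called 41 genes between genotypes under vehicle and 82 under Ang II. In both 10 were called: Cybb (-1.88 and -1.73), Stx8 (-2.49 and -2.43), Cxcl13 (-1.55 and -1.70), Coch (-2.14 and -2.61), Gpx3 (-1.43 and -1.70) and Rilpl2 (-1.47 and -1.38), lower in knockout cells, and Cyb5r4 (1.32 and 0.88), Lamtor2 (1.12 and 0.83), Hscb (1.13 and 0.89) and Zfp87 (1.55 and 0.91), higher. Stx8, Coch and Gpx3 averaged below 5 in knockout cells. Under vehicle Gpx3 averaged below 5 in wild-type cells too (4.62, n = 7). Gpx3 on wild-type vehicle replicates 6 and 7 (3.25, 3.78) and Cxcl13 on replicate 7 (5.41) lay at or below knockout levels. In that fit the stroma list had a median of -0.46 under vehicle (camera adjusted p = 0.000660; 0.0439 with an estimated correlation) and -0.54 under Ang II (1.36e-06; 0.00149).

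Gene families were counted with Hyd/HCTZ against Ang II relative to the median shift, where 2472 of all 10452 tested genes rose and 2611 fell. Of 37 proteasome subunit genes 27 rose and 0 fell (camera adjusted p = 4.65e-08), of 7 chaperonin genes 5 rose and 0 fell (0.0248), and of 52 genes of ribosomal proteins 13 rose and 8 fell (0.0248). Of 68 microRNA genes 50 fell and 10 rose (7.27e-10), and of 43 small nucleolar RNA genes 15 fell and 6 rose (0.00539). None passed with an estimated correlation (adjusted p = 0.191 to 0.586). These arrays alone formed array set 3.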
